A study of Arabidopsis thaliana with 9 samples.

How the data were processed

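Transcript levels were measured on 1-colour Affymetrix arrays in root tips, 3 mm long, of Arabidopsis thaliana seedlings 5 days old. There were 9 arrays, 3 for each of 3 genotypes: wild type of the Col-0 accession, a line with a T-DNA insertion in ERF115, and a line that overexpresses ERF115 from a constitutive viral promoter. ERF115 encodes a transcription factor of the ethylene response factor family. Per the labels' protocols the tips were cut with scalpels, frozen in liquid nitrogen and not treated, and biotin-labelled RNA was prepared with a 3' in vitro transcription kit. The deposited values are on the log2 scale, and per the submitters' processing notes the authors made them with RMA in affy 1.36. RMA corrects the background, sets all arrays to a common distribution and summarises the probes of a probe set over all arrays together, so a change shared by most transcripts would be removed from the values, and small differences in probe sets close to background are compressed. Values that were equal in every deposited digit occurred on at least 2 arrays for 56.5% of the probe sets tested. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

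The deposited table held 22810 probe sets. The 64 control probe sets were left out of all tests, which leaves 22746. Genes were named through the platform's probe table and the RefSeq gene table of assembly TAIR10.1, which was used for names only. Of the probe sets tested, 13513 have 1 gene there, 503 have several and 8730 are unnamed here, and 13436 of those with 1 gene matched the gene table, at 13286 loci. No probe set was named from several genes. The ERF115 transcript was not analysed here, because no probe set was named as ERF115 through these tables. The labels of the mutant and the overexpressor were therefore not checked against the level of that gene. No genome build is given in the sources used here for the array design, so no coordinates are printed.

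Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per genotype, all 9 arrays and a spread shared by the 3 genotypes. There were 6 residual and 4.49 prior degrees of freedom. The 3 pairs of genotypes were compared, and p-values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets of a comparison, with a threshold of 0.05. Log2 fold changes are given with their standard error (SE), and levels as mean ± SD over 3 arrays. The number of arrays limits the precision: the median SE of a log2 fold change was 0.088. On simulated data with the real means and spreads of the 22746 probe sets, the fit of overexpressor against wild type called 65% of genes changed by 0.5 and 96% of those changed by 1 on the log2 scale, and 4.17% of its calls were unchanged genes. These simulated probe sets were independent of each other, unlike real ones.

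The comparisons, the model, 28 gene lists and the rule for naming genes were fixed beforehand. The rule names, per comparison, the 10 largest increases and 10 largest decreases among probe sets with 1 gene that passed the threshold and whose 3 values in each genotype did not overlap, and up to 4 members of each list with the smallest p. Where fewer than 5 probe sets passed, the 5 with the smallest p are named. ERF115, which the rule also names, was not analysed here. Of the 363 genes on the lists, 49 could be named on a probe set with 1 gene. The fixed rule left out 6 of these (ERF114, ERF112, WIND3, WIND4, SAND and TIP41), because the gene table does not give their symbol or alias for the locus, so 43 were used. The rest may lie on probe sets that are unnamed here or have several genes. List genes called measured are therefore only those named and used. At least 1 member was measured for 18 lists and at least 3 for 5 lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. No member was left for ERF group X, root cap, jasmonate, auxin synthesis and transport, indole glucosinolate, DNA damage response, endodermis, xylem, heat shock and reference genes.

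Several choices were made only after the first fit and its leading genes had been seen. These are 7 further gene lists, written from memory of gene families (class III peroxidases, extensins, root hair specific, iron deficiency, berberine bridge enzyme-like, early mechanical stress responders and dividing cell genes), 2 covariates, a split of the wild-type arrays between mutant and overexpressor, a scan of 37 families of probe sets whose gene symbols start with the same letters, a version of the list tests with at least 3 members, 1 that keeps the 6 genes above, 1 without probe sets whose name marks shared probes, and 1 of the further lists without genes named by size in either comparison of the overexpressor. None of the root hair specific genes was named here, so that list was not tested. The minimum of 3 members and the keeping of the 6 genes had at first been used for all list tests, after their effect on the lists was known, and were set back to alternatives because neither belonged to the fixed design. Shared probes as an explanation of the extensin values were first read as argued against and, after the value was seen, as open, and the limit on how far a covariate may follow genotype was also set after its effect was seen. A first simulation of comparisons with shared wild-type arrays, built from regrouped residuals, was degenerate and was replaced by arrays drawn with the covariance within genotypes, which led to the same reading. The other alternatives, chosen before the data were examined, were median centring, quantile normalization, 2 filters on low values, a trended and robust prior, array weights, only the 6 arrays compared, the replicate number as a block, a fold threshold, a stricter threshold and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.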

Results

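The transcriptomes of root tips with a disrupted or an overexpressed ERF115 gene were set against wild type, to find which transcripts depend on this transcription factor. The data are log2 RMA values of 22746 probe sets on 9 arrays, 3 each of wild type, erf115 mutant and ERF115 overexpressor. Array medians lay between 5.045 and 5.13. Correlations across probe sets were 0.9955 to 0.9981 between arrays of the same genotype, 0.9962 to 0.9977 between wild type and mutant, and 0.9902 to 0.9955 between the overexpressor and the others. Probe sets are not independent replicates in these correlations. The first principal component held 46.1% of the variance. The overexpressor arrays lay at 16.6 to 29.8 on it, the wild type at -15.8 to -8.0 and the mutant at -13.8 to -5.5. The 3'-to-5' difference of the actin control probe sets, a sign of RNA quality, was 2.20 ± 0.12 in wild type, 2.22 ± 0.03 in the mutant and 2.04 ± 0.09 in the overexpressor (log2, SD, n = 3). With 3 arrays against 3, an exact two-sided permutation test cannot go below p = 0.1, and it gave p = 0.2 for overexpressor against wild type and p = 0.1, the smallest possible, for overexpressor against mutant, which differed by -0.18. The GAPDH control probe sets showed no such shift, with 0.20 ± 0.03 in wild type, 0.20 ± 0.10 in the mutant and 0.19 ± 0.07 in the overexpressor.

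**Figure D1:**
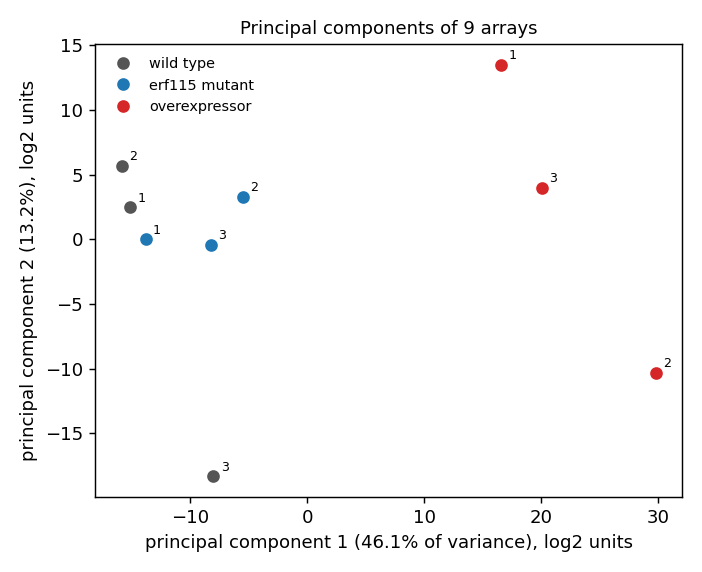
Each point is 1 of 9 arrays on the first (46.1% of variance) and second (13.2%) principal components of the log2 values, coloured by genotype and numbered by replicate. The 3 overexpressor arrays lie at 16.6 or above on the first component, and wild type and mutant arrays lie at -5.5 or below.

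The overexpressor was first compared with wild type. The 10 largest named increases included 3 class III peroxidases and a cell wall enzyme, and the 10 largest named decreases included 3 genes of calcium-binding proteins. The largest named increase was in AT4G36430, a class III peroxidase, with 3.58 ± 0.03 in wild type and 6.66 ± 0.39 in the overexpressor, an 8.50-fold difference (log2 fold change 3.09, SE 0.17, adjusted p = 7.15e-06). The peroxidases AT5G39580 and AT1G34510 rose by 2.72 (SE 0.23) and 2.26 (SE 0.41). XTH20, a xyloglucan endotransglucosylase of the cell wall, rose 4.58-fold (2.19, SE 0.19, adjusted p = 0.000142). AT2G39690 (5.27-fold, SE 0.11 on the log2 scale), AT3G13980 (2.29, SE 0.10) and AT3G47510 (1.68, SE 0.28) also rose, as did AT4G25790, of the CAP and PR-1-like family (1.78, SE 0.26), and the berberine bridge enzyme-like genes AT1G30760 (1.69, SE 0.25) and AT1G30700 (1.62, SE 0.16).

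The largest named decrease was in AT4G29780, from 7.20 ± 0.40 in wild type to 5.31 ± 0.61 in the overexpressor (-1.89, SE 0.33, adjusted p = 0.00792). The calmodulin-like gene CML23 (-1.55, SE 0.18) and the EF-hand genes AT4G27280 (-1.50, SE 0.17) and AT1G76640 (-1.47, SE 0.20) fell. ATGSTF13, a glutathione transferase, decreased by 1.55 (SE 0.13), and EXO, known to act in cell expansion, decreased by 1.29 (SE 0.10). AT1G72240, AT3G19680, AT4G27652 and AT4G27654 completed the 10 largest decreases, with log2 fold changes of -1.54, -1.30, -1.19 and -1.13. The largest increase of all was in an unnamed probe set, by 7.88 (SE 0.11, adjusted p = 3.45e-11). It stood at 2.17 ± 0.02 in wild type, where 4.11% of the probe sets were lower still, and at 10.06 ± 0.17 in the overexpressor. RMA compresses differences at such low levels, so 7.88 is no exact size. Another unnamed probe set rose by 3.40, more than any named gene, and the largest decrease of all, by 2.25 (SE 0.25), was also in an unnamed one.

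**Figure D2:**
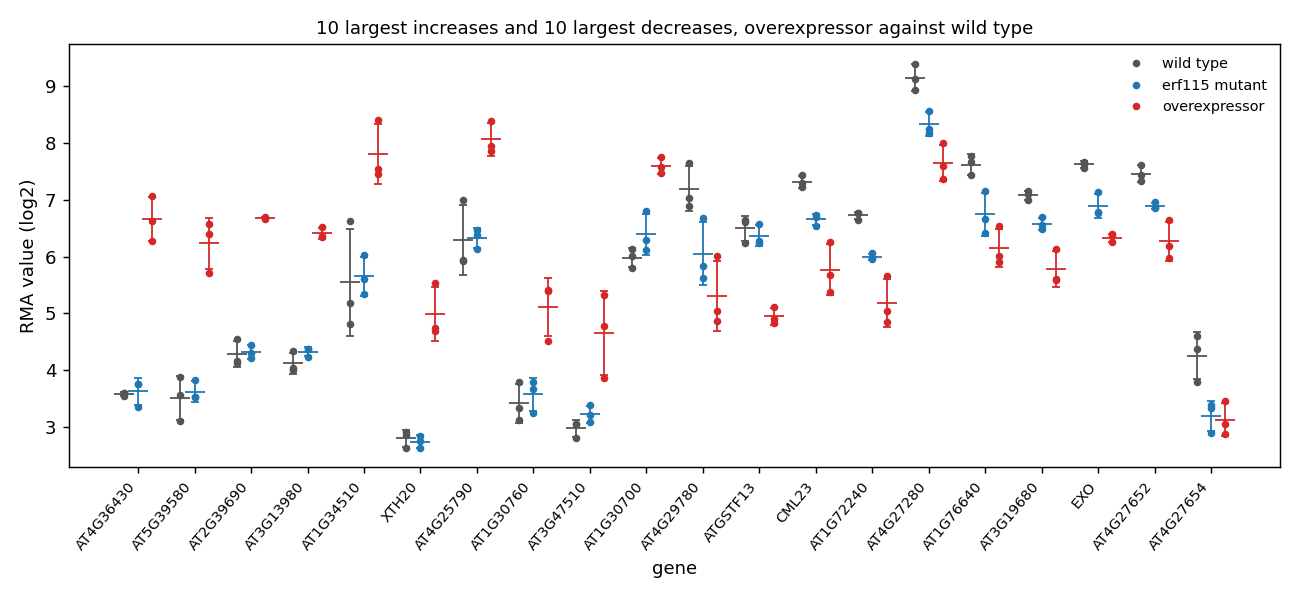
Dots are the 3 arrays of each genotype, horizontal marks the mean and bars the SD of log2 RMA values, for the 10 largest named increases and 10 largest named decreases in overexpressor against wild type. AT4G36430 stood at 6.66 in the overexpressor and 3.58 in wild type, and CML23 at 5.77 and 7.31.

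In all, 854 of 22746 probe sets were higher and 387 lower in the overexpressor than in wild type, with 158 and 24 of these changed at least 2-fold. Higher calls made up 68.8% as deposited and 56.7% with each array centred on its median. Without wild-type replicate 1, 522 were higher, without wild-type replicate 2, 540 were higher, and without overexpressor replicate 3, 226 were lower. With the mean of EXPA7 and EXPA18 per array as a covariate, chosen after the data were seen, 5 were higher and 0 lower, and with the mean of STZ, CML37 and CML38 as a covariate 40 and 4. Both means differ mostly between genotypes, which hold 89.7% of the variance of the first and 76.4% of that of the second.

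Of the lists fixed in advance, root hair and epidermis, cell wall loosening, lignin and PSK signalling passed with higher values, and touch and rapid wound response passed with lower values. With an estimated correlation none of the 4 lists tested passed: adjusted p = 0.16 for root hair, 0.26 for cell wall loosening, and 0.21 for both lignin and touch, while PSK signalling, with a single gene, could not be tested this way. The 2 measured root hair genes, the expansins EXPA7 (0.81, SE 0.08, adjusted p = 0.000438) and EXPA18 (0.85, SE 0.17, adjusted p = 0.0137), both rose (camera adjusted p = 0.0012). Of 8 cell wall loosening genes, 3 rose, namely XTH20, EXPA7 and EXPA18, and 5 did not pass; XTH21 stood at -0.28 (SE 0.07, adjusted p = 0.0562) and passed as lower with median centring, quantile normalization, either filter on low values, a trended prior or array weights, or without mutant replicate 1 (adjusted p 0.022 to 0.05). Adjusted over the list alone, 3 were higher and 1 was lower (camera adjusted p = 0.034). Without XTH20 the list had a median of 0.13 and an unadjusted camera p of 0.11. HCT, of lignin synthesis, rose by 0.40 (SE 0.09, adjusted p = 0.035), and CCR2 stood at 0.45 (SE 0.12, adjusted p = 0.0685; camera adjusted p = 0.023 for both). PSY1R, a receptor kinase and the 1 measured member of PSK signalling, rose by 0.56 (SE 0.10, adjusted p = 0.00773), and its list rests on that gene (camera adjusted p = 0.038). No probe set with 1 gene was named here as a PSK, PSKR or TPST gene of that list, so its call says nothing of them. They may lie on unnamed probe sets. STZ, a zinc finger protein (-1.12, SE 0.21, adjusted p = 0.0105), and CML38 (-1.07, SE 0.20, adjusted p = 0.0117) fell, and CML37 stood at -0.26 (SE 0.08, adjusted p = 0.0913, or 0.049 without wild-type replicate 1; camera adjusted p = 0.0031). The mean of these 3 touch genes was 4.85 ± 0.24 in wild type, 4.39 ± 0.21 in the mutant and 4.03 ± 0.24 in the overexpressor, in tips that were cut at harvest (exact permutation test, two-sided, p = 0.1 for each line against wild type, the smallest possible). Adjusted over the list alone, 2 root hair and 2 lignin genes were higher and 3 touch genes lower, while for PSY1R, alone in its list, that adjustment leaves the unadjusted p. With the median filter on low values cell wall loosening (mean 0.21 in place of 0.46, adjusted p = 0.39), lignin (0.14) and PSK signalling (0.1) lost their call, and with the log2 filter cell wall loosening (0.35), lignin (0.15) and touch (0.15) did. These filters also take members out of the lists. XTH20 was removed by both, the filtered lignin mean was the 0.40 of HCT, and the touch mean under the log2 filter was the -1.12 of STZ. PSK signalling lost its call without wild-type replicate 1 (adjusted p = 0.076) or 2 (0.063) or overexpressor replicate 1 (0.058), 2 (0.064) or 3 (0.062), and cell wall loosening without wild-type replicate 1 (0.088) or 2 (0.063) or overexpressor replicate 1 (0.052). EXPA18 lost its call without wild-type replicate 1 (adjusted p = 0.052), without wild-type replicate 2 (0.06), without overexpressor replicate 2 (0.055) and with only the 6 arrays compared (0.053). HCT lost its call without wild-type replicate 1 (0.12), wild-type replicate 2 (0.11), mutant replicate 3 (0.062), overexpressor replicate 1 (0.094) or overexpressor replicate 2 (0.11), and with only the 6 arrays compared (0.078).

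Among 6 stem cell niche genes, AGL42, a MADS-box gene of the quiescent centre, fell by 0.52 (SE 0.09, adjusted p = 0.00789), and 5 did not pass, among them BBM (-0.30, SE 0.14) and AT5G41920 (-0.26, SE 0.10), which passed without overexpressor replicate 1 (adjusted p = 0.044). That list had a camera adjusted p of 0.26, and AGL42 alone was lower adjusted over the list alone. With fry, which tests whether the genes of a list move and not whether they differ from other genes, the list passed as lower (adjusted p = 0.018, and 0.017 against the mutant). None of the 3 measured G2 and M phase genes passed: AUR1 stood at -0.15 (SE 0.07), AUR2 at 0.06 (SE 0.08) and AUR3 at 0.07 (SE 0.10). Their median was 0.06 and their mean -0.01, with a camera adjusted p of 0.95. None of the 8 auxin response genes passed, with a median of 0.01. The remaining lists held 1 or 2 measured genes, none of which passed in the main fit. RR16 (0.24, SE 0.08) did pass without overexpressor replicate 1 (adjusted p = 0.046) and, against the mutant, with array weights (0.048). Adjusted over the list alone, RR16 of the cytokinin response list was higher, and for that list the camera direction was up and the median below 0. SIM, alone in the list of CDK inhibitors and APC activators, had an unadjusted p under 0.05 and did not pass over all probe sets. The median log2 fold changes of the remaining lists were 0.16 for wound and regeneration regulators, -0.01 for S phase, 0.21 for CDK inhibitors and APC activators, -0.12 for brassinosteroid, -0.10 for ethylene, -0.02 for cytokinin response, 0.39 for defence, -0.19 for flavonoid, 0.12 for phloem and 0.15 for photosynthetic tissue. These small values depended on single arrays: with 1 array left out, defence lay between 0.16 and 0.58, flavonoid between -0.31 and -0.05, and brassinosteroid between -0.23 and 0.01.

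**Figure D3:**
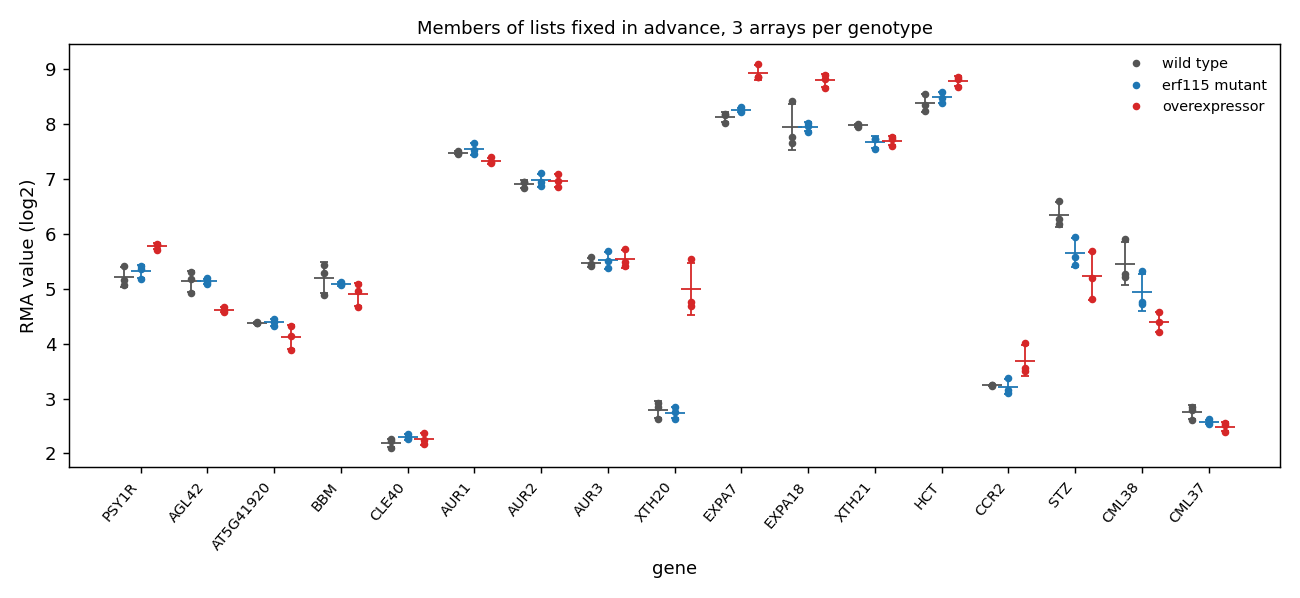
Dots are the 3 arrays of each genotype, horizontal marks the mean and bars the SD of log2 RMA values, for members of 6 gene lists fixed in advance. Up to 4 members per list are shown, those with the smallest p in overexpressor against wild type. Other members of the larger lists are left out. EXPA7 stood at 8.94 in the overexpressor and 8.13 in wild type, and STZ at 5.23 and 6.35.

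The erf115 mutant was compared with wild type next, and 3 of 22746 probe sets differed. AT5G35940, a jacalin-related lectin, fell from 9.55 ± 0.22 in wild type to 8.45 ± 0.14 in the mutant (-1.10, SE 0.11, adjusted p = 0.0117), and its value in the overexpressor against wild type was 0.35 (SE 0.11, adjusted p = 0.104). An unnamed probe set rose by 1.11 (SE 0.09, adjusted p = 0.00483) and another fell by 0.62 (SE 0.07, adjusted p = 0.0317), and in the overexpressor these rose by 1.02 (SE 0.09) and fell by 1.09 (SE 0.07) against wild type. Next by p came EXO (-0.73, SE 0.10) and AT3G20340 (0.54, SE 0.07), neither of which passed, at an adjusted p of 0.071 each. Both passed with either filter on low values, a trended prior or array weights (adjusted p 0.016 to 0.046 for EXO and 0.024 to 0.044 for AT3G20340). EXO also passed with median centring (0.039), with quantile normalization (0.048) and without mutant replicate 1 (0.019). In limma 1033 of 22746 probe sets had an unadjusted p under 0.05, a share below the 0.05 that unchanged probe sets would give on average. All 3 calls were lost without wild-type replicate 2 or mutant replicate 3, that of AT5G35940 also without wild-type replicate 1 (adjusted p = 0.1), mutant replicate 2 (0.12) or overexpressor replicate 1 (0.056), and that of the lower unnamed probe set without any single array other than mutant replicate 1 and overexpressor replicate 2. The lower unnamed probe set also lost its call with a trended prior (0.062), and with only the 6 arrays compared it (0.11) and AT5G35940 (0.13) did not pass. With the mean of the 3 touch genes as a covariate 0 probe sets passed. Without mutant replicate 1, 5 probe sets were lower, and without overexpressor replicate 2, 3 were.

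No member of a fixed list passed in the mutant. The touch and rapid wound response list passed as a group with lower values (camera adjusted p = 0.00098), with STZ at -0.69 (SE 0.21), CML38 at -0.52 (SE 0.20) and CML37 at -0.17 (SE 0.08). With an estimated correlation the adjusted p was 0.42. CML38 stood at -0.30 without wild-type replicate 2. Adjusted over the list alone, 2 of these and 2 cell wall loosening genes were lower. WRKY53 (0.69, SE 0.24) and RCA (0.27, SE 0.11), each alone in its list, had an unadjusted p under 0.05 and did not pass over all probe sets. EXPA7 stood at 0.13 (SE 0.08) and XTH20 at -0.06 (SE 0.19). Cell wall loosening passed as lower with the log2 filter (adjusted p = 0.04), and the 0.69 of WRKY53, alone in the defence list, passed as a list without wild-type replicate 2 (0.043), mutant replicate 3 (0.019) or overexpressor replicate 3 (0.048). RCA, alone in the list of photosynthetic tissue, did so without mutant replicate 1 (0.015).

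The overexpressor was also compared with the mutant. Wild-type arrays enter this comparison through the shared spread and not through the fold changes. The actin 3'-to-5' difference was 2.04 ± 0.09 in the overexpressor and 2.22 ± 0.03 in the mutant, with no overlap between their arrays. That of GAPDH was 0.19 ± 0.07 and 0.20 ± 0.10. AT4G36430 (3.04, SE 0.17), AT5G39580 (2.61, SE 0.23), AT2G39690 (2.36, SE 0.11), XTH20 (2.25, SE 0.19), AT1G34510 (2.15, SE 0.41), AT3G13980 (2.09, SE 0.10) and AT4G25790 (1.73, SE 0.26) rose here too. AT1G47400 (1.68, SE 0.13), AT1G55200 (1.64, SE 0.09) and AT1G33590, a leucine-rich repeat protein (1.61, SE 0.13), completed the 10 largest named increases. Unnamed probe sets rose by more, the largest increase of all being again in that with the low wild-type level, by 7.89. Among named genes, ATGSTF13 fell by 1.42 (SE 0.13), the GDSL lipase gene AT3G16370 by 1.12 (SE 0.11), XTH16 by 0.81 (SE 0.08) and GH9C3, an endoglucanase, by 0.80 (SE 0.10). The other 6 of the 10 largest named decreases were in AT5G22580, AT1G64910, CML23, AT1G72240, AT3G19680 and AT2G40250, with log2 fold changes of -0.94, -0.90, -0.89, -0.82, -0.80 and -0.79.

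In this comparison 602 probe sets were higher and 235 lower, and with array weights 1079 and 683, which lowers the share of higher calls from 71.9% to 61.2%. Of these, 542 were also higher and 173 also lower against wild type, where 22.6 and 4 would be shared by independent lists. These comparisons share the overexpressor arrays, which raises the overlap by an amount not estimated here. In 100 simulations of unchanged groups the overlap had a median of 0 and was at most 1 in each direction. Unchanged groups have few calls to share, so these simulations do not measure what the shared arrays add. Fewer were called without mutant replicate 1 (280 higher, 75 lower), mutant replicate 3 (287 and 87), overexpressor replicate 2 (366 and 135) or overexpressor replicate 3 (377 and 111), and with the covariates above 7 and 0 (root hair genes) or 204 and 43 (touch genes) were called. Cell wall loosening (camera adjusted p = 3.9e-05), root hair and epidermis (0.00039) and lignin (0.025) passed with higher values. With an estimated correlation they had adjusted p = 0.10, adjusted p = 0.10 and adjusted p = 0.17. HCT (0.30, SE 0.09) and CCR2 (0.48, SE 0.12), the 2 lignin genes, did not pass singly, though CCR2 did with array weights (adjusted p = 0.035), and that list lost its call without mutant replicate 1 (adjusted p = 0.066), with array weights (0.062) and with the median (0.23) or log2 filter (0.22). Under either filter the list mean was the 0.30 of HCT. Without XTH20, cell wall loosening had a median of 0.12 and an unadjusted camera p of 2e-04. EXPA7 rose by 0.68 (SE 0.08), EXPA18 by 0.84 (SE 0.17) and PSY1R by 0.46 (SE 0.10), and AGL42 fell by 0.51 (SE 0.09). Calls were lost without mutant replicate 1 for AT1G34510, AT1G64910, CML23, AT1G72240, AT2G40250, PSY1R, AGL42 and EXPA18 (adjusted p 0.051 to 0.13), and without mutant replicate 3 for CML23, AT1G72240, AT2G40250, PSY1R and EXPA18 (0.057 to 0.11). They were also lost for AT1G34510, CML23 and AT1G72240 without mutant replicate 2 (0.053 to 0.067), for AT1G72240, AT2G40250, PSY1R and EXPA18 without overexpressor replicate 1 (0.05 to 0.07), for AT1G34510, AT2G40250, PSY1R and EXPA18 without replicate 2 (0.067 to 0.099), and for CML23, AT1G72240, AT2G40250 and PSY1R without replicate 3 (0.068 to 0.093). With only the 6 arrays compared, CML23 (0.06) and AT1G72240 (0.064) did not pass.

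In limma 0 probe sets passed in opposite directions in mutant and overexpressor, each against wild type, but 1 did with median centring or array weights and 2 with a trended prior. There were 25 at an unadjusted p under 0.05 in both, while 211 were higher in both and 256 lower in both. Independent lists would share 50.7 in the higher direction and 43.6 in the lower. In 100 simulations of unchanged groups that share the wild-type arrays the medians were 25 and 23.5, and the highest values 2300 and 2850, with a median of 0 and a highest value of 177 for opposite directions. The fold changes correlated across probe sets at 0.42 (simulated median 0.56), with a covariance of 0.0112 (simulated median 0.00621). With the wild-type arrays split 1 against 2, so that the comparisons shared no array, the 6 possible splits gave covariances of -0.00229 to 0.00797, with a mean of 0.00452. In 27 of 100 simulations of unchanged groups the mean was as large. This split was chosen after the data were seen.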

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

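The 2 covariates, the list tests with at least 3 members, with the 6 left-out genes, without shared probes and without the largest genes of either overexpressor comparison were chosen after the data had been seen. No called gene or list turned its direction under any alternative run without a covariate. There, single arrays left out included, 92 of the tests of named genes lost and 27 gained a call. Of the list tests, 55 lost and 30 gained one. The outcome was unchanged in 2464 gene tests and 1676 list tests. Among the losses, 18 of genes under the fold threshold were by construction. So were 15 of genes and 5 of lists at an adjusted p under 0.01. The cause of the other changes was not tested unless stated. Centring on reference genes was not run, because no reference gene was left, and the ERF115 transcript was not analysed here.

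For overexpressor against wild type (854 higher, 387 lower), a fold threshold left 158 and 24 and an adjusted p under 0.01 left 410 and 139, both by construction. The 6 arrays alone gave 226 lower, and leaving out 1 array gave 522 to 976 higher and 226 to 377 lower. For overexpressor against mutant (602 and 235), these thresholds left 107 and 4, and 222 and 54. Array weights gave 1079 and 683, and leaving out 1 array 280 to 695 and 75 to 262. For the mutant (1 higher, 2 lower), the higher count was 2 with median centring or the median filter and 3 with a trended prior or array weights. The lower count was 4 with the log2 filter or the trended prior, 7 with array weights, 1 with the fold threshold, and 0 with 6 arrays or at 0.01. Leaving out 1 array gave 0 to 1 higher and 0 to 5 lower. At an adjusted p under 0.05, 0 probe sets moved in opposite directions in mutant and overexpressor, against 1 with median centring or array weights, 2 with the trended prior and 0 to 0 with 1 array left out. At an unadjusted p, 25 did.

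With the replicate number as a block, 885 and 379, 633 and 214, and 1 and 1 probe sets were called. Under the block HCT (adjusted p = 0.057) and the lower unnamed probe set of the mutant (0.19) no longer passed, while CCR2 passed in both comparisons of the overexpressor (0.039 and 0.038) and LBD16 in that with the mutant (0.032). The numbers did not pair overexpressor and wild type, where same-numbered deviations correlated at -0.212 to 0.058. For mutant and wild type a weak pairing stays possible. Their same-numbered deviations correlated at 0.138, 0.12 and 0.096, and each array correlated best with its own number.

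Of fixed lists, 5, 1 and 3 passed for overexpressor against wild type, mutant against wild type and overexpressor against mutant. An estimated correlation left 0, 0 and 0, though PSK signalling, with 1 gene, was not tested by it. For the first, 2 passed with the median filter, at 0.01 or with at least 3 members, 1 with the log2 filter, 6 with directional fry and 3 with mixed fry. For the second, 2 passed with the log2 filter and 0 with either fry. For the third, 5 passed with directional fry and 1 with at least 3 members. Stem cell niche passed in both comparisons of the overexpressor with directional fry and with mixed fry (adjusted p = 0.0062 and 0.0096). Leaving out 1 array gave 3 to 5, 1 to 2 and 2 to 4.

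Both covariates are largely set by genotype (89.7% and 76.4% of their variance). The root hair covariate left 5 higher and 0 lower against wild type, 7 and 0 against the mutant, 1 lower in the mutant, and 0, 2 and 0 lists. Against wild type it turned AT1G34510 (-0.74), AT4G25790 (-0.29), HCT (-0.18), and the mean of lignin (-0.11), class III peroxidases (-0.20) and berberine bridge enzyme-like genes (-0.02). Against the mutant it turned AT1G34510 (-0.61), AT4G25790 (-0.16), PSY1R (-0.03), lignin (-0.10) and class III peroxidases (-0.19). The values of EXPA7 and EXPA18, whose mean is the covariate, must sum to 0 under it, so those of EXPA18 (-0.44 and -0.34) are no turn. Cell wall loosening, which holds both, had means of -0.05 and 0.07. The handling covariate left 40 and 4, 204 and 43, 0 and 0 in the mutant, and 1 and 0 lists for the first 2 comparisons with wild type. This covariate is the mean of the 3 touch genes, so the 0.00 of their list is fixed and the 0.01 of CML38 is no turn. The early mechanical stress list, with a mean of 0.03, holds these 3 genes too.

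RMA values near the low end of the scale limit the fold changes of low genes: XTH20 stood at 2.80 in wild type, where the lowest value on any array was 1.59.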

Other observations

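The lists of added genes, the family scan, the 2 covariates and the tests of differentiated tissue and of shared wild-type arrays were chosen only after the results had been seen. The added lists were prompted by the leading genes of the overexpressor, so they are not independent evidence. Where a list holds genes named by size in either comparison of the overexpressor, here called prompting genes, a second value leaves them out. The other members were also chosen after the first fit had been seen, so that value is no independent check either.

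Of 9 measured extensins, structural proteins of the cell wall, 6 were higher in the overexpressor than in wild type and none lower, with a median log2 fold change of 0.70. AT4G08410 rose by 1.25 (SE 0.24), AT3G54580 by 0.99 (SE 0.16) and AT3G28550 by 0.70 (SE 0.09). The list's camera adjusted p was 3.6e-08 with the preset correlation, and adjusted p = 0.052 with an estimated correlation (against the mutant, adjusted p = 0.032). None of these 9 was among the prompting genes, so there is no second value for this list. The list was still written after the first fit had been seen, so its p-values are not free of that choice. Of 54 class III peroxidases, 12 were higher and 3 lower (median 0.09), and adjusted p = 0.0013 became adjusted p = 0.21 with an estimated correlation. Without the prompting genes, 9 of 51 were higher and 3 lower (median 0.05, adjusted p = 0.033, or adjusted p = 0.36 with an estimated correlation). Of 8 iron deficiency genes, AT1G47400 (1.61, SE 0.13), AT5G05250 (1.38, SE 0.19) and AT3G07720 (0.54, SE 0.12) rose, with adjusted p = 0.006, or adjusted p = 0.074 with an estimated correlation. Without AT1G47400, a prompting gene, 2 of 7 were higher (median 0.13), and the list no longer passed (adjusted p = 0.11, or adjusted p = 0.34 with an estimated correlation), nor did the list as cut by the median filter on low values (0.054). Of 22 berberine bridge enzyme-like genes 3 were higher (adjusted p = 0.015, or adjusted p = 0.18 with an estimated correlation), and 1 of 20 without the prompting genes (adjusted p = 0.17). None of 9 dividing cell genes, none of them prompting, passed (median -0.13, camera adjusted p = 0.15). That list did pass as lower with the log2 filter (mean -0.11, adjusted p = 0.047), and, against the mutant, without mutant replicate 2 (0.034). Mixed fry, which has no direction, gave 0.041 against wild type. In the mutant none of the members of these 5 lists passed.

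Of 37 families formed from the first letters of gene symbols, 1 passed camera for overexpressor against wild type, 2 for overexpressor against mutant and none for mutant against wild type. The one that passed in both comparisons of the overexpressor holds 8 probe sets whose symbols share only the letter G, which is no gene family. The other, the EXPA expansins, had adjusted p = 0.042 against the mutant and adjusted p = 0.24 against wild type.

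The higher extensin values stayed under median centring and quantile normalization of the deposited values, with a median of 0.67 at its lowest. Both steps were applied to values that the authors had already normalized. They therefore cannot tell whether the authors' normalization contributed. Probes shared between extensin paralogs stay open: the 5 extensins whose probe sets carry no mark of shared probes had a median of 0.24, against 0.70 for all 9, and exceeded the bound set beforehand by less than the median SE of 0.13, and 4 of the 6 that rose carry that mark. Against them as the whole cause, all 5 lay above 0, AT3G54580 and AT3G28550 among them rose, and the 5 passed as a list (adjusted p = 0.0015, or adjusted p = 0.074 with an estimated correlation). This was at first read as arguing against shared probes, and was read as open after the value was seen. A larger share of differentiated tissue in the overexpressor tips may also contribute, as the median was 0.03 (median SE 0.28) with the mean of EXPA7 and EXPA18 as a covariate. That covariate cannot be told apart from genotype, which holds 89.7% of its variance, so an effect of ERF115 on these genes stays equally open.

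Of 20 early mechanical stress responders, 11 were lower and 2 higher in the overexpressor (median -0.81). Without the prompting genes, 5 of 14 were lower and 2 higher (median -0.43). These 14 still hold the 3 genes of the fixed touch list, and STZ (-1.12) and CML38 (-1.07) are among the 5 lower ones. The 14 are therefore no independent check. With an estimated correlation the list had adjusted p = 0.18. None passed singly in the mutant, where the median was -0.49, but 14 of 20 were lower adjusted over the list alone, and the list had camera adjusted p = 3.3e-21, or adjusted p = 0.12 with an estimated correlation. Without the prompting genes the mutant median was -0.32 (unadjusted camera p = 3.9e-12 with the preset correlation). The list was prompted by decreases in the overexpressor against the same 3 wild-type arrays. High values on those arrays would lower the list in both lines, so the mutant values are not independent of that choice. Between overexpressor and mutant 3 were higher and 2 lower (median -0.27, camera adjusted p = 0.073, or adjusted p = 0.54 with an estimated correlation), and 3 and 0 without the prompting genes (median -0.12). The list passed as lower there without wild-type replicate 2 (adjusted p = 0.047), mutant replicate 2 (0.034) or 3 (0.011) or overexpressor replicate 2 (0.00031), and its mean of -0.20 ranged from -0.32 to -0.08 over the arrays left out. Against wild type, the overexpressor median was -0.84 or lower under median centring and quantile normalization of the deposited values. The authors had already normalized these values, so both scalings cannot tell whether that normalization contributed. Handling of the tips at harvest is a candidate explanation: the genes deviated together between arrays of the same genotype, with a mean pairwise correlation of 0.53 against a 95th percentile of 0.08 in 1000 random lists of similar level. Genes under common control in the plant would also do so, and an effect of genotype on them was not separated from handling.

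Mutant and overexpressor fold changes tended to the same sign. Shared wild-type arrays may account for this, since the covariance of 0.0112 lay below the highest simulated one of 0.0297, with a simulated median of 0.00621. With no wild-type array shared, the mean covariance was 0.00452, and 27 of 100 simulations without an effect gave as much, so a shared effect of both lines is neither shown nor excluded.

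The 6 arrays of each comparison allow 10 splits, too few for a share under 0.05. The real split called 1241 probe sets for overexpressor against wild type, 837 for overexpressor against mutant and 3 for mutant against wild type, and the highest of the other splits called 0 in each, so that 1 split of 10 reached the real value.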
